A study of Mus musculus with 12 samples.

How the data were processed

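Reduced representation bisulfite sequencing was carried out on DNA of sorted leukaemia cells from mouse spleens. Bisulfite turns unmethylated cytosines into uracil and leaves methylated ones, so each read that crosses a CpG calls it methylated or unmethylated. The method sequences restriction fragments and favours CpG-dense DNA. The 12 libraries fall into 3 groups of 4 by the labels.

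The deposited files hold counts: for each CpG cytosine and strand, the number of reads that call it methylated and the number that call it unmethylated, one library per file and not normalised. Per the submitters' processing notes, the tools were Trim Galore 0.6.4, cutadapt 2.7, Bismark and methylKit 1.20.0, with the mouse build mm10. The version and settings of Bismark, the removal of duplicate reads and the conversion rate are not given in the sources used here. The deposited counts list cytosines with at least 1 call, so a CpG missing from a file had no call there. Reads carry no molecular identifiers that the files keep, so copies of one molecule can be counted more than once, and the intervals given cover counting error only.

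The calls of both strands of a CpG were summed. The libraries listed 13236795 CpGs in all, of which 1052856 on the autosomes and X had at least 10 calls in each of the 12 libraries, with a median of 84 calls per CpG and library. These common CpGs gave 87020 non-overlapping tiles of 1000 bp with at least 3 CpGs (median 6 CpGs and 663 calls). The plan named windows around the start of each gene, but the gene table used (GRCm38.p6, the same build as mm10) gives no strand. Windows of 1000 bp on each side were therefore placed at the annotated gene end that held more common CpGs, for protein-coding genes, and are called gene ends here. A gene end is thus a start for some genes and a stop for others. Of 21631 protein-coding genes, 13855 had a gene end with at least 3 common CpGs (median 30 CpGs and 2924 calls), and 2464 had enough CpGs at both ends. The mean methylation of PBS was under 20% at 79.7% of the gene ends. For the classes of CpGs, a gene-end CpG was called dense with at least 25 listed CpGs within 250 bp on each side and sparse otherwise. Exons and introns were not used here, so the rest of each gene and the DNA outside genes formed the other classes (382427 dense, 60587 sparse, 366739 in the rest of genes and 243103 outside genes).

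Mean methylation was averaged over the common CpGs for each library, and groups were compared by two-sided exact permutation tests over the 70 assignments, with Benjamini-Hochberg adjustment over the 3 comparisons (for classes, over classes and comparisons). CpGs, tiles and gene ends were tested by a quasi-binomial logistic model of methylated against unmethylated counts with an F test. Its Pearson dispersion was moderated by empirical Bayes, the method of limma's squeezeVar, within bins of mean methylation bounded at 5%, 20%, 80% and 95%, and was not allowed under 1. A call needed an adjusted p under 0.05 and a difference of the group means of at least 10 percentage points. Only the 8 libraries of the groups compared entered a test. The step was tested on simulated data at 13855 gene ends: for CD11b-positive against PBS it recovered 50 of 100 gene ends changed by 15 points and 72 of 100 changed by 30 points, with 1 false call. For CD11b-negative against PBS it recovered 49 and 69 with 2 false calls, and for CD11b-positive against CD11b-negative 38 and 68 with 4 false calls. The simulated noise was independent between gene ends, without shifts shared across a library. The counts of false calls may therefore not hold for the real libraries.

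The 17 gene lists were tested on log2((methylated + 1) / (unmethylated + 1)) per gene end with limma's fry, whose directional p asks whether the members move, on balance, one way, with adjustment over the lists. They are antigen presentation, monocyte and macrophage, dendritic cell, neutrophil, TLR9 and NF-kB signalling, STAT3 pathway and targets, DNA methylation machinery, stem cell and leukaemia, interferon-stimulated, tumour suppressors methylated in leukaemia, germline, imprinted, T and NK cell, B cell, erythroid and megakaryocyte, stromal and endothelial, and housekeeping genes. limma's camera with a preset correlation of 0.01 and with an estimated correlation was run beside it. The tests, lists, naming rule and most of the alternatives were fixed before the data were examined.

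Genes were named by rule. For each comparison these were the 10 called gene ends with the largest gain and the 10 with the largest loss whose libraries did not overlap between groups, 20 genes given whether called or not, and in each list the called member with the largest gain and the largest loss. The 20 genes were Irf8, Itgam, Dnmt1, Dnmt3a, Dnmt3b, Stat3, Socs3, Tlr9, Spi1, Cebpa, Csf1r, Itgax, Cd86, Ciita, H2-Ab1, Runx1, Cbfb, Myh11, Kit and Gata2. Tiles were named as the 3 largest gains and 3 largest losses without overlap. Other called list members are named where a count is 5 or less, and 1 gene end is not reported here.

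The labels share replicate numbers between groups without saying what a number marks. The deviations of same-numbered CD11b-positive and CD11b-negative libraries from their group means over tiles correlated with r = 0.159, 0.926, 0.654 and 0.682 for numbers 1 to 4, all over the bound of 0.1, so these groups were also fitted with the number as a block. The pairing thus comes from the data and not from the labels. The libraries numbered 2 stood far from the rest of both groups, which alone can give such r without pairing. Only 1 CD11b-positive library correlated best with the CD11b-negative library of its own number. Other alternatives changed the coverage minimum, depth, window, tile size, dispersion, threshold, test (edgeR's quasi-likelihood test) and chromosomes, or left out each library in turn. Fits without the libraries numbered 2, with lncRNA genes, and with calls on 8 single-copy Y genes per 1000000 autosomal calls (the Y share) as a term in a fit of all 12 libraries were added after seeing the data. The mean chi-square per tile of the 18 pairs of libraries within groups ran from 2.21 to 83.8. All CpGs on Y and the mitochondrial genome stayed out of the tests. The programs were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.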

Results

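The series profiled DNA methylation in CMM cells, a GFP-positive mouse line that models acute myeloid leukaemia with inv(16), engrafted by vein into C57BL/6 mice. When about 1% of blood cells were GFP-positive, mice received PBS or CpG-STAT3dODN, a CpG oligonucleotide joined to a STAT3 decoy, in 3 intravenous injections given every other day. Spleens were taken 1 day after the last injection. GFP-positive cells were sorted from the PBS mice, and GFP-positive cells with or without the myeloid surface marker CD11b from the treated mice, giving 4 libraries in each of 3 groups (PBS, CD11b-negative, CD11b-positive). The libraries held 112671408 to 157223205 methylation calls. The labels do not say that libraries of a group came from separate animals, so p-values measure only the spread between these libraries. The stated question was whether DNA methyltransferases change in the CD11b-positive subset relative to the CD11b-negative bulk or to untreated cells.

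The comparison of CD11b-positive with PBS cells asks how the treated CD11b-positive subset differs from untreated leukaemia cells. PBS cells were not sorted by CD11b, so a treatment effect and the selection for CD11b cannot be told apart here. The CD11b-positive libraries carried more DNA methylation than the PBS libraries on average over the common CpGs, and less at CpG-dense gene ends. Methylation rose by 50.3 and 48.0 points at the gene ends of Rhd and Ermap, which encode red blood cell surface proteins, and by 46.5 points at Hdac7, a histone deacetylase gene. The erythropoietin receptor gene Epor and the haematopoietic cofactor gene Lmo2 also gained methylation. It fell by 40.2 points at Dlk1, an imprinted gene, and by 41.3 points at Hs3st4, a heparan sulphate sulphotransferase gene. In a fit of all 12 libraries Rhd, Ermap, Hdac7 and Epor stayed called and Lmo2, Dlk1 and Hs3st4 did not. With the share of calls on Y genes (the Y share) as a further term, added after the data were seen, Rhd and Ermap stayed called. Hdac7 (32.1 points, adjusted p = 0.0504), Epor (17.6, adjusted p = 0.0869) and Lmo2 (11.7, adjusted p = 0.0675) were then not called, nor were Dlk1 and Hs3st4, which changed sign (9.997 and 5.53 points). The gene ends of Irf8, Dnmt3b and Stat3 had low methylation in both groups, at most 5.36%, and none of them was called. A loss could not be called at these levels, since a call needed 10 points.

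Mean methylation over the common CpGs was 34.7% ± 0.810 in CD11b-positive and 31.4% ± 0.292 in PBS (SD, n = 4 each), a difference of 3.32 points with every CD11b-positive library above every PBS library (two-sided exact permutation p = 0.0286, the smallest that 70 assignments allow, adjusted p = 0.0429). Methylation rose most in the DNA outside genes, from 56.5% ± 0.927 to 65.4% ± 2.76, followed by the rest of genes, from 43.5% ± 0.619 to 48.8% ± 1.58, and CpG-sparse gene ends, from 19% ± 0.203 to 21.3% ± 0.575. At CpG-dense gene ends it dropped from 5.88% ± 0.598 to 3.83% ± 1.14. Each of the 4 classes separated the groups completely (exact permutation p = 0.0286, adjusted p = 0.0490). All 4 missed the threshold on autosomes only (adjusted p = 0.0571), without any 1 PBS library (0.0857 to 0.171) and without CD11b-positive 2 (0.0571 to 0.0980). On autosomes only the differences were -1.79 points at CpG-dense and 2.63 at CpG-sparse gene ends, against -2.05 and 2.25 with X. The adjusted p also depends on the other comparisons, since the adjustment covers all classes and comparisons. Calls were made at 176008 CpGs (139442 higher, 36566 lower), 31537 tiles (28266 higher, 3271 lower) and 1521 gene ends (851 higher, 670 lower). The groups did not overlap at 30.3% of all gene ends, where chance gives 2.86%, and at 1502 of the 1521 called. Of the 416 gene ends measured on X, 85 were called, 11 higher and 74 lower.

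**Figure D1:**
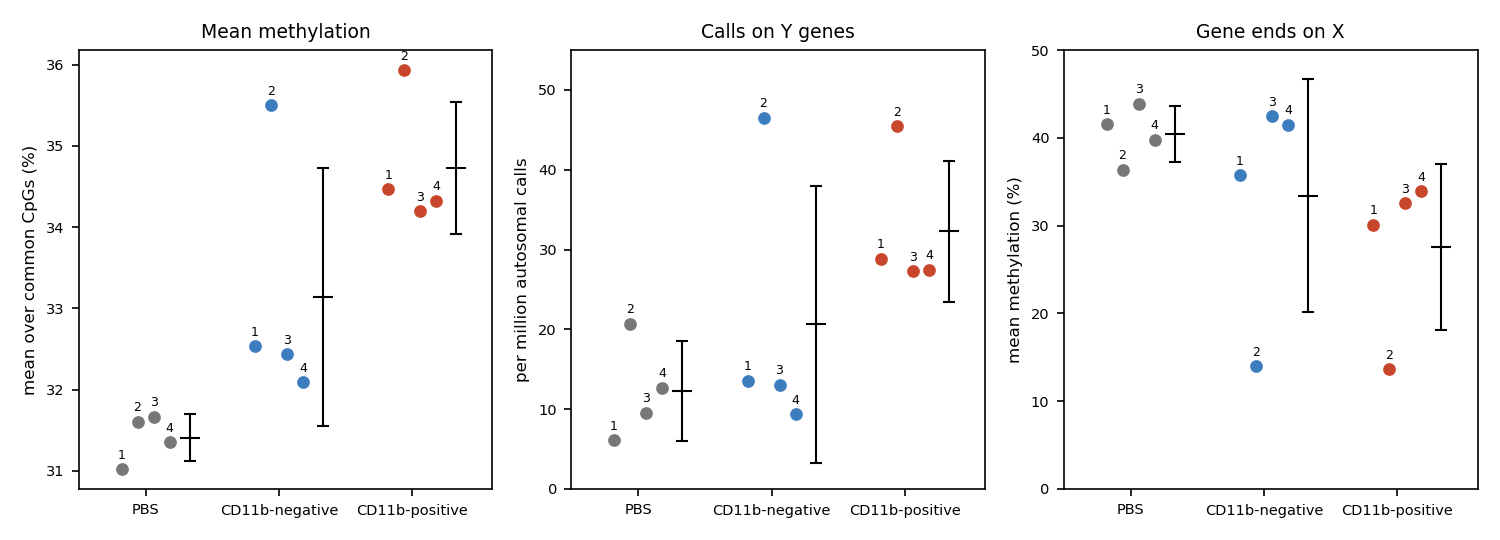
Each point is 1 library with its replicate number, and the bar beside each group is the mean ± SD of 4 libraries. The panels show mean methylation over the common CpGs in percent, calls on Y genes per 1000000 autosomal calls and mean methylation of gene ends on X in percent. All CD11b-positive libraries lie above the PBS libraries in mean methylation and in Y calls, and CD11b-negative 2 lies at 35.5% and at 46.5 Y calls per 1000000.

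The largest gene-end gains (mm10) were at Tnni3, cardiac troponin I (chromosome 7, 4521718 to 4523718, 4 CpGs with 40 to 110 calls per library), with 79.7% ± 14.2 in CD11b-positive against 19.6% ± 16.4 in PBS (adjusted p = 0.0240). Rhd (chromosome 4, 134863536 to 134865536) rose from 9.60% ± 3.63 to 59.9% ± 13.1 (adjusted p = 0.00241), Ermap (chromosome 4, 119189013 to 119191013) from 8.06% ± 2.74 to 56.1% ± 13.5 (adjusted p = 0.00293) and Hdac7 (chromosome 15, 97843502 to 97845502) from 5.92% ± 4.22 to 52.4% ± 6.45 (adjusted p = 0.00206). Spata25, Gdf3, Dapp1, Poglut3, 4930415O20Rik and Spata46 gained between 43.7 and 50.6 points. The largest losses were at Sgsm1 (chromosome 5, 113309788 to 113311788), from 69.8% ± 15.7 to 23.9% ± 20.3 (adjusted p = 0.0428), and at Gm40864, Ccdc60, Hs3st4, Gm4767, Gm9222, Dlk1, Apba2, Kazn and Slc2a13, with differences from -44.5 to -39.6 points. With the Y share as a term all of these but Gm40864 and Gm4767 changed sign, as did the gain at 4930415O20Rik, and none of those was called. Dlk1 (chromosome 12, 109451485 to 109453485) had 70.6% ± 8.02 in PBS and 30.3% ± 22.4 in CD11b-positive (adjusted p = 0.0299). Among tiles, the largest gains lay in Tbxas1 (thromboxane synthase, chromosome 6, 38921001 to 38922000, 13% to 75.6%), in Parp14 (chromosome 16, 35857001 to 35858000, 9.16% to 70.9%) and 49774 bp from Phc1 (chromosome 6, 122390001 to 122391000, 4.77% to 64.6%). The largest tile losses lay in Sgsm1 (chromosome 5, 113310001 to 113311000, 69.8% to 23.9%), 24203 bp from Chsy1 (chromosome 7, 66198001 to 66199000, 75.8% to 30.8%) and in Gm9222 (chromosome 12, 17881001 to 17882000, 72.7% to 28.1%).

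Of the 20 genes fixed for the question, 14 had a measured gene end, and Itgam, Dnmt1, Dnmt3a, Cd86, H2-Ab1 and Runx1 had none. The windows of Ciita, Spi1, Tlr9, Itgax and Csf1r lay at the gene end with the higher coordinate. Those of Irf8, Cebpa and Dnmt3b lay at the lower one. Without the strand, each may be a gene start or a gene stop, so these values are not promoter methylation by definition. Ciita, the MHC class II transactivator, rose from 66.6% ± 2.44 to 83.6% ± 3.95 (adjusted p = 0.0143), and Spi1, which encodes the myeloid transcription factor PU.1, from 78.6% ± 0.586 to 89.5% ± 4.03 (chromosome 2, 91114759 to 91116759, adjusted p = 0.0125), in a stretch that held fewer calls in PBS. Irf8, a transcription factor of monocyte and dendritic cell development, had 5.36% ± 0.985 in PBS and 3.38% ± 1.32 in CD11b-positive (chromosome 8, 120735358 to 120737358, adjusted p = 0.0309), a difference of -1.98 points that was under the 10 points a call needed. Cebpa had 2.15% and 1.45% (adjusted p = 0.0212) and Tlr9, the receptor of CpG DNA, 4.66% ± 1.12 and 10.7% ± 3.33 (adjusted p = 0.0280), and both differences were also under 10 points. Dnmt3b, a de novo DNA methyltransferase, had 0.607% ± 0.115 and 0.541% ± 0.267 (adjusted p = 0.835), and Stat3 had 0.595% and 0.571% (adjusted p = 0.943). Itgax had 71.1% and 85.6% (adjusted p = 0.0629) and Csf1r 71.4% and 78.8% (adjusted p = 0.429). Cbfb (chromosome 8) and Myh11 (chromosome 16) are the mouse counterparts of the genes that inv(16) joins in human leukaemia. Cbfb had 0.593% and 0.518% (adjusted p = 0.445) and Myh11 5.52% and 7.96% (adjusted p = 0.302). Neither was called, nor were Kit, Gata2 and Socs3.

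**Figure D2:**
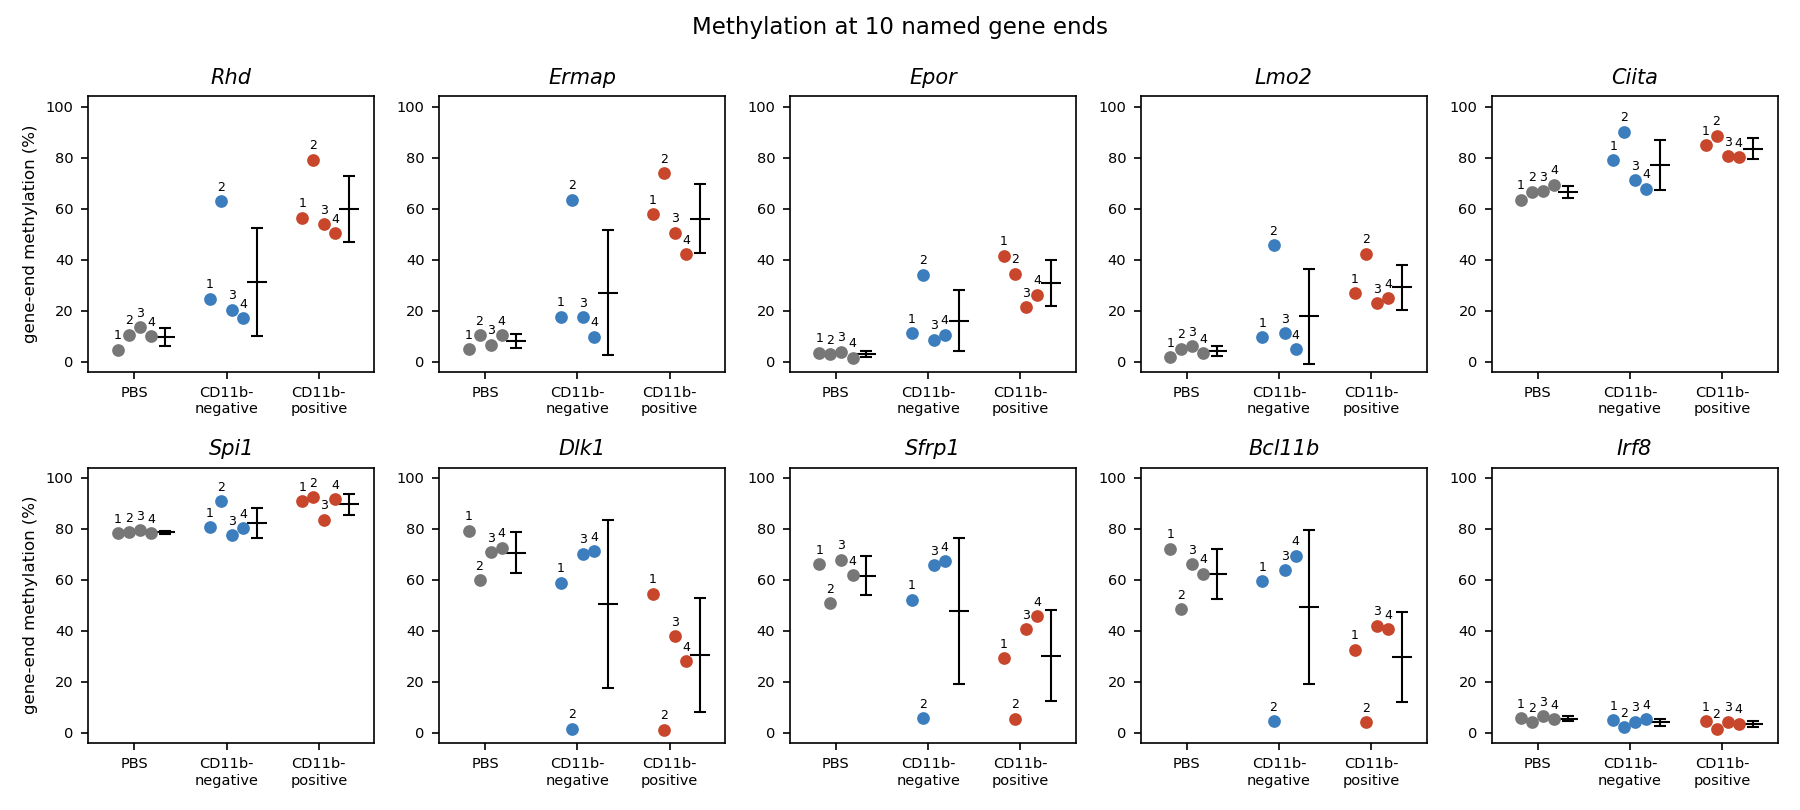
Each point is the methylation of 1 gene end in 1 library, in percent, with its replicate number, for 10 named genes in the 3 groups, and the bar beside each group is the mean ± SD of 4 libraries. The means of Rhd are 9.60% in PBS and 59.9% in CD11b-positive, and those of Irf8 5.36% and 3.38%.

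Among the gene lists, 5 passed fry's directional test with members higher on balance. This test does not compare members with other gene ends, so it cannot tell a change of the list from a shift shared by many gene ends. The median difference of the members was 0.282 points in the T and NK cell list, 0.574 in the stromal list and 1.04 in the erythroid and megakaryocyte list. It was 4.61 in the germline list and 12.02 in the B cell list. With camera's estimated correlation none of the 5 list calls held. The adjusted p was 0.316 with an estimated correlation for the erythroid and megakaryocyte list, 0.663 for the germline and B cell lists and 0.968 for the T and NK cell and stromal lists. With the preset correlation the germline and the erythroid and megakaryocyte lists held. In the erythroid and megakaryocyte list (adjusted p = 0.00146), 2 of 9 measured members rose, Epor from 2.92% ± 1.07 to 30.9% ± 8.96 (chromosome 9, 21962576 to 21964576) and Nfe2, with 2 also higher adjusted over the list alone. In the germline list (adjusted p = 0.0101), Tex19.1, Tex101, Hormad1 and Brdt rose among 17, Brdt from 61.8% to 82.2%, and 5 were higher adjusted over the list alone. In the T and NK cell list (adjusted p = 0.0101) Zap70, a T cell receptor kinase, rose from 45.8% to 73.5% and Gata3 rose, whereas Bcl11b, a T cell transcription factor, fell from 62.2% to 29.7%, among 13 (2 higher and 1 lower adjusted over the list alone). In the B cell list (adjusted p = 0.0101) Blk, a B cell kinase, rose from 30.9% to 52.8% and Cd72 rose, among 4 (both also adjusted over the list alone). In the stromal and endothelial list (adjusted p = 0.0141) Pecam1 rose from 7.39% to 30.2% and Madcam1 rose, and the chemokine gene Cxcl12 fell from 44.8% to 19.9%, among 9 (2 higher and 1 lower adjusted over the list alone).

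The other 12 lists did not pass the directional test, although the STAT3 pathway and dendritic cell lists (adjusted p = 0.00440 for both) and the stem cell and leukaemia list (0.0473) did with windows of 2000 bp outside and 500 bp inside the gene. In antigen presentation (adjusted p = 0.219), H2-DMb1, H2-Oa, Ciita and Tapbp were higher among 13, H2-DMb1 at 68.3% against 39.7% in PBS, and 4 also adjusted over the list alone. The monocyte and macrophage list (16, adjusted p = 0.921) held 1 member higher, Spi1, and 1 lower, with the same counts adjusted over the list alone. The dendritic cell list (15, adjusted p = 0.399) held Zbtb46 and Wdfy4 higher, Wdfy4 at 58.9% against 20.4%, and Cadm1 lower, 12% against 25.2% (3 higher and 1 lower adjusted over the list alone). The stem cell and leukaemia list (25, adjusted p = 0.0864) held Hoxa7, Hoxa9 and Lmo2 higher, Lmo2 at 29.2% ± 8.87 against 4.02% ± 1.99 (chromosome 2, 103956903 to 103958903), with 3 higher and 1 lower adjusted over the list alone. The neutrophil list (8, adjusted p = 0.695) held Elane, neutrophil elastase, higher, 71.2% against 48.2%, with 3 higher adjusted over the list alone. TLR9 and NF-kB signalling (25, adjusted p = 0.399) held Nfkb2 higher, 88.0% against 75.6%, with 1 higher adjusted over the list alone. The interferon-stimulated list (11, adjusted p = 0.265) held Oasl1 higher, 87.4% against 76.5%, and DNA methylation machinery (20, adjusted p = 0.921) held Zbtb33, which lies on X, lower, 19.3% against 39.5%, and neither call held adjusted over the list alone, where both counts were 0. Tumour suppressors methylated in leukaemia (20, adjusted p = 0.695) held Sfrp1 and Id4 lower, Sfrp1 at 30.1% against 61.6%, and imprinted genes (19, adjusted p = 0.265) held Magel2 and Dlk1 lower, with 2 lower each adjusted over the list alone. The STAT3 pathway (22, adjusted p = 0.102) and housekeeping (14, adjusted p = 0.628) lists held no called member, also adjusted over the list alone. In these lists 19 and 12 members had a mean under 5% over the 12 libraries, where a loss could not be called. The direction of fry's test was up for the tumour suppressors and down for the monocyte list, where the means of the differences were -3.71 and 0.0593 points, and up for the STAT3 pathway, with a mean of -0.141 and a median of 0.0554 points.

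Calls on 8 single-copy Y genes were 32.3 ± 8.82 per 1000000 autosomal calls in CD11b-positive and 12.2 ± 6.25 in PBS (exact permutation p = 0.0286, adjusted p = 0.107 over 15 tests). Methylation of gene ends on X was 27.5% ± 9.42 and 40.4% ± 3.17 (exact permutation p = 0.0286, adjusted p = 0.107). A fit of all 12 libraries called 36 gene ends and 75828 CpGs, and 34 of the 44 named gene-end and tile calls ended. Its tile calls stayed within 1.5-fold of the 31537 called from the 8 libraries. With the Y share as a further term, 5 gene ends, 467 tiles and 2946 CpGs were called, and 39 of the 44 named calls ended. The gene ends were Rhd, Ermap, Snx1, Nme9 and Slc22a3, the last 3 named after their values were seen. On the log scale 1 list was called with the term (erythroid and megakaryocyte, fry's adjusted p = 0.0170). edgeR's quasi-likelihood test called 839 gene ends (689 higher, 150 lower) and 30796 tiles. Without PBS 1, 3 or 4 the gene-end calls were 274 (255 higher, 19 lower), 345 (318 and 27) and 324 (293 and 31), and without CD11b-positive 1 they were 734 (606 and 128), so most of the lower calls ended. Leaving out PBS 1, 2, 3 or 4 ended 25, 4, 23 and 23 of the 44 named calls and leaving out CD11b-positive 1, 2, 3 or 4 ended 15, 3, 1 and 6. The Spi1 call ended without CD11b-positive 2 (9.98 points, adjusted p = 0.0132) and the Ciita call without PBS 1 (16.0 points, adjusted p = 0.0515). Without PBS 1 the T and NK cell and stromal lists (adjusted p = 0.0526 for both) were not called, and without CD11b-positive 1 the stromal list was not (adjusted p = 0.0787) and TLR9 and NF-kB signalling was (adjusted p = 0.0308). Without PBS 3 the STAT3 pathway list was called too (adjusted p = 0.0237).

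The comparison of CD11b-negative with PBS cells asks whether the treated cells without the marker differ from untreated ones. Here too the treatment cannot be told apart from the sorting by CD11b. The CD11b-negative libraries also carried more methylation on average than PBS, but no gene end, tile or CpG passed the quasi-binomial test and no gene list passed fry's. Mean methylation was 33.1% ± 1.59 against 31.4% ± 0.292, a difference of 1.73 points (two-sided exact permutation p = 0.0286, adjusted p = 0.0429). Weighted by depth it was 0.458 points (adjusted p = 0.83). CpG-sparse gene ends had 20.3% against 19%, the rest of genes 46.1% against 43.5% and the DNA outside genes 61.1% against 56.5% (exact permutation p = 0.0286, adjusted p = 0.0490 for each), and CpG-dense gene ends 4.95% against 5.88% (exact permutation p = 0.486). Without CD11b-negative 2 the differences were 0.671 points at CpG-sparse gene ends (adjusted p = 0.0381), 1.18 in the rest of genes and 2.14 outside genes (adjusted p = 0.0623 for both). Without any 1 PBS library none of the 3 was called. Gene-end methylation of Irf8 was 4.07% ± 1.38 against 5.36% ± 0.985 (adjusted p = 0.864), of Dnmt3b 0.689% against 0.607% (adjusted p = 0.876), of Tlr9 5.72% against 4.66% (adjusted p = 0.865) and of Ciita 77.0% ± 9.92 against 66.6% ± 2.44 (adjusted p = 0.864).

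The quasi-binomial test called 0 CpGs, 0 tiles and 0 gene ends, with 52881, 8615 and 726 at an unadjusted p under 0.05, and edgeR called 0 tiles and 0 gene ends, with 5663 and 676 at an unadjusted p under 0.05. limma's fry called 0 lists, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.496, and camera called 1 with the preset correlation (erythroid and megakaryocyte) and 0 with the estimated one. CD11b-negative 2 stood apart from the other libraries of its group, with a mean methylation of 35.5% against 32.1% to 32.5% and 46.5 Y calls per 1000000 against 9.38 to 13.6. Without it 15 CpGs, 3 tiles (chromosome 2, 5805001 to 5806000, chromosome 5, 112969001 to 112970000, and chromosome 17, 45684001 to 45685000, named after their values were seen) and the erythroid and megakaryocyte list (adjusted p = 0.0273) were called, all higher, and the mean difference was 0.942 points. Without CD11b-negative 3, 7 CpGs were called.

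The comparison of CD11b-positive with CD11b-negative cells asks what differs between the 2 subsets under treatment. Between the sorted fractions of the treated mice no gene end, tile, CpG or list passed the unpaired tests, whereas many gene ends, tiles and CpGs did with the replicate number as a block. Mean methylation was 34.7% ± 0.810 in CD11b-positive and 33.1% ± 1.59 in CD11b-negative (difference 1.59 points, two-sided exact permutation p = 0.114). CD11b-positive was higher for each replicate number, by 1.93, 0.431, 1.77 and 2.23 points (exact sign-flip permutation p = 0.125, the smallest that 4 pairs allow). The Y share in CD11b-positive and CD11b-negative was 28.9 and 13.6 for number 1, 27.3 and 13.1 for number 3, and 27.5 and 9.38 for number 4. For number 2, with the smallest methylation difference, it was 45.5 and 46.5. These pair differences therefore cannot tell the sorted fraction apart from the Y share. Gene-end methylation was 3.38% ± 1.32 and 4.07% ± 1.38 at Irf8 (adjusted p = 0.599), 0.541% ± 0.267 and 0.689% ± 0.176 at Dnmt3b (adjusted p = 0.711), 10.7% ± 3.33 and 5.72% ± 1.24 at Tlr9 (adjusted p = 0.522) and 83.6% ± 3.95 and 77.0% ± 9.92 at Ciita (adjusted p = 0.593). CD11b-positive was higher at Tlr9 and lower at Irf8 for all 4 numbers. With the number as a block the adjusted p was 0.0749 at Tlr9 and 0.240 at Irf8. By class, the exact permutation p ran from 0.114 to 0.371. Within each class the 4 numbers had differences of 1 sign, negative at CpG-dense gene ends and positive elsewhere.

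The quasi-binomial test called 0 CpGs, 0 tiles and 0 gene ends, with 71713, 9372 and 978 at an unadjusted p under 0.05, and edgeR called 0 tiles and 0 gene ends, with 2971 and 528. limma's fry called 0 lists, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.207, and camera called 0 with either correlation. With the replicate number as a block, 72228 CpGs (53894 higher in CD11b-positive, 18334 lower), 11790 tiles (10076 higher, 1714 lower) and 683 gene ends (201 higher, 482 lower) were called. This block rests on a pairing that the labels do not give. It also does not separate the sorted fraction from the Y share, which was higher in CD11b-positive for numbers 1, 3 and 4. Without CD11b-negative 2, the unpaired test called 77083 CpGs, 17798 tiles, 234 gene ends (163 higher, 71 lower) and 3 lists (T and NK cell, erythroid and megakaryocyte, stromal and endothelial), the mean difference was 2.38 points (exact permutation p = 0.0286), and all 4 classes were called (adjusted p = 0.0381).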

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

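The fit with the Y share was added after the data were seen, the tests on its count of gene-end calls and on the count of differing tiles were set out before those counts were seen, and all other tests below, with the splits of the libraries, were chosen after the results were seen.

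One library lay far from the other 3 of its group in 29 of 198 groups of 4, where chance gives about 5% for independent groups. These groups are measures of the same 12 libraries, many of them named for large differences, so the 5% is no yardstick for the count. Of the 29, 15 were CD11b-negative 2. That library had a mean methylation of 35.5% (others 32.1% to 32.5%), 22.0% at CpG-sparse gene ends (19.5% to 19.9%), 50.6% in the rest of genes (44.2% to 45.1%) and 46.5 Y calls per 1000000 autosomal calls (9.38 to 13.6). Its gene ends stood apart at Bcl11b with 4.36% (59.3% to 69.4%), Dapp1 with 84.0% (25.9% to 33.7%), Elane with 91.9% (44.8% to 49.6%), Epor with 34.0% (8.52% to 11.2%), Ermap with 63.5% (9.69% to 17.6%), Lmo2 with 45.5% (4.84% to 11%), Nfkb2 with 91.6% (74.9% to 77.3%), Oasl1 with 97.3% (72.8% to 74.8%), Rhd with 62.8% (17% to 24.7%), Spata25 with 79.3% (16.4% to 26.7%) and Spata46 with 85.5% (13.1% to 24.4%). CD11b-positive 2 stood apart within its group with a mean of 35.9% (34.2% to 34.5%), 22.1% at CpG-sparse gene ends (20.9% to 21.1%), 51.2% in the rest of genes (47.8% to 48.4%), 69.5% outside genes (63.7% to 64.6%) and 45.5 Y calls per 1000000 (27.3 to 28.9). Its gene ends did so at Gdf3 with 75.1% (53.5% to 56.4%), Poglut3 with 77.1% (48.8% to 53.4%), Wdfy4 with 82.4% (48.8% to 53.2%), Zap70 with 89.1% (66.2% to 69.7%) and Zbtb33 with 1.05% (24.8% to 25.6%). The others were CD11b-positive 3 at Socs3 with 2.15% (2 of 93 calls, the others 0%), PBS 2 at Cxcl12 with 32.1% (47.8% to 50.2%) and Tlr9 with 6.33% (4.01% to 4.17%), and PBS 1 at Myh11 with 7.13% (4.84% to 5.18%). The 95% Wilson intervals of these single-library gene-end shares were 0.788 to 11.4 points wide. The 4 CD11b-positive libraries also had more calls on single-copy Y genes than any PBS library (mean 32.3 per 1000000, PBS 6.07 to 20.7). Methylation was not tested on the Y chromosome.

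The design offers a biological explanation for the higher methylation of CD11b-positive, a difference between the sorted fraction and untreated leukaemia cells, which stays open and untested. Incomplete conversion is argued against by a difference of 0.0778 points in methylated calls on the largely unmethylated mitochondrial genome, while a link with CpGs of 1 call cannot be told apart, since their share was 41.6% to 47.9% in 3 CD11b-positive libraries and 30.5% to 34.2% in PBS, and only CD11b-positive 1, with a share of 8.75% and a mean of 34.5%, went against it. A candidate explanation is DNA of XY cells other than the leukaemia cells, which the GFP gate would remove, while the labels do not give the sex of the line or the recipients. It fits that, in linear fits of all 12 libraries, the median change at the 1521 called gene ends, in the direction of the call, dropped from 20.5 to 3.18 points with the Y share as a term (median standard errors 7.06 and 3.05), although the term also removes any real difference that goes with the Y share, and the drop to 5 gene-end calls decides nothing, since a fit of all 12 libraries without the term had called 36. Over the 7 PBS and CD11b-negative libraries other than CD11b-negative 2, the distance in autosomal methylation from PBS towards it rose with the Y share. Spearman's rho was 0.857 (exact permutation p = 0.0238) and Pearson's r 0.781 (exact permutation p = 0.0429). Without PBS 1 and 2, over 5 libraries, rho was 0.7 and r 0.711.

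CD11b-negative 2 resembled CD11b-positive 2 more than its own group. By tile methylation, a second copy of the same library under both names could not be told apart from 2 alike libraries. In this pair 30 tiles differed by 25 points or more (11 to 435 in pairs of PBS libraries). The mean chi-square per tile was 2.29 (2.40 to 10.4). Calls on the mitochondrial genome argue against such a copy for these 2 libraries. They were 20465 beside 112671408 calls in all in CD11b-negative 2, and 6226 beside 133623666 in CD11b-positive 2. A share of XY cells stays open, because the 46.5 Y calls per 1000000 are one of the values that set CD11b-negative 2 apart. Calls on X relative to the PBS mean were 0.581 and methylation of X gene ends was 14.0% in CD11b-negative 2. CD11b-positive 2 had 0.590 and 13.6%, and the other CD11b-negative libraries 0.892 to 1.01 and 35.8% to 42.5%. These X values go the same way as the Y calls, and no test was set on them. A mixed-up sort and a fraction that truly differed stay open, and no biological explanation was tested.

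On the log scale, the erythroid and megakaryocyte gene ends were the list whose call was left with the Y share as a term. By fry's test its adjusted p was then 0.0170 on the log scale and 0.0591 on the percent scale, where a mixture of cells is linear. On the percent scale the germline list was called instead (fry's adjusted p = 0.0190), and the T and NK cell and B cell lists also had 0.0591. Epor stood at 41.5% in CD11b-positive 1, with 28.9 Y calls per 1000000, against 34.0% and 34.5% in the libraries with the most Y calls, CD11b-negative 2 and CD11b-positive 2. XY cells and a change in the leukaemia cells cannot be told apart for the erythroid and megakaryocyte list. The scales differ and 1 library decides the Epor level.

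For CD11b-positive against PBS, 1 of 35 splits of the 8 libraries, the real one, gave as many calls, the smallest share that 35 splits allow. It called 176008 CpGs against at most 0 in any other split, 31537 tiles against 0, 1521 gene ends against 0 and 5 lists against 2. These counts come from the same 8 libraries and the test was chosen after the results were seen, so chance is not excluded. For CD11b-negative against PBS and for CD11b-positive against CD11b-negative the real split gave 0 calls, which each of the 35 of 35 splits reaches by definition, so the count says nothing about chance. The highest other split was 0 CpGs, 1 tile, 0 gene ends and 0 lists for the first, and for the second the split that exchanged CD11b-negative 2 with CD11b-positive 4 called 65965 CpGs, 18123 tiles, 121 gene ends and 4 lists where the real split called 0, which points to a structure of the samples. With the block, the 8 splits that part all 4 pairs are too few for a share under 0.05; the real split alone (1 of 8) reached 72228 CpGs, 11790 tiles and 683 gene ends, and the highest other, which exchanged the libraries numbered 2, gave 34684, 6395 and 525.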

How the results depend on the processing

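Fits with the Y share and without the libraries numbered 2, and the count with lncRNA genes, were chosen after the results were seen; the other alternatives were planned. The cause of each change below was not tested unless given.

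The mean difference of CD11b-positive from PBS, 3.32 points, kept its sign throughout and missed the threshold with coverage in 3 of 4 libraries per group (3.62, adjusted exact permutation p = 0.0857), weighted by depth (5.10, 0.0857), with the replicate block (3.32, sign-flip p = 0.125, the smallest possible) and without the 3 libraries numbered 2 (2.98, 0.1, the smallest possible with fewer libraries). For CD11b-negative against PBS these values were 1.54, 0.458, 1.73 and 1.01 (adjusted p = 0.114, 0.83, 0.125 and 0.1), and weighted by depth CD11b-positive against CD11b-negative gave 4.64 (1.59 in the report, adjusted p = 0.171). Leaving out 1 library gave 2.92 to 3.50 for CD11b-positive against PBS, 0.942 to 2.08 for CD11b-negative against PBS and 1.19 to 2.38 for CD11b-positive against CD11b-negative; without any 1 PBS library the first 2 missed the threshold (adjusted p = 0.0857 for CD11b-positive, 0.114 without PBS 1 and 0.0857 without PBS 2, 3 or 4 for CD11b-negative), and without CD11b-negative 2 the last passed it (2.38, exact permutation p = 0.0286).

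All 4 classes of CD11b-positive against PBS, and the 3 called for CD11b-negative against PBS, kept their sign. They missed the threshold with coverage in 3 of 4 libraries, on autosomes only, without any 1 PBS library and in both fits without libraries numbered 2. Without CD11b-positive 2 the 4 of the first missed it, and without CD11b-negative 2 the rest of genes and the DNA outside genes of the second (adjusted p = 0.0623). In all, 36 values of the first and 26 of the second missed it. Without CD11b-negative 2 all 4 classes of CD11b-positive against CD11b-negative passed it (adjusted p = 0.0381). The classes were not run with the block or weighted by depth.

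For CD11b-positive against PBS, calls were 0 CpGs and 216 gene ends (209 higher, 7 lower) without moderation of the dispersion, 75828 CpGs and 36 gene ends (33 higher, 3 lower) with all 3 groups in 1 fit, 62397 CpGs, 7233 tiles and 32 gene ends at an adjusted p under 0.01 and 25 points, 51914 tiles and 3650 gene ends with no minimum difference, 2782 gene ends with lncRNA genes, 839 gene ends with edgeR, and 2946 CpGs, 467 tiles and 5 gene ends with the Y share. Leaving out 1 library gave 119251 to 172257 CpGs, 27174 to 32073 tiles, 274 to 1467 gene ends (274, 345, 324 and 734 without PBS 1, 3, 4 and CD11b-positive 1) and 3 to 6 lists (3 without PBS 1). Lists numbered 8 with the window of 2000 bp outside and 500 bp inside (also STAT3 pathway, dendritic cell and stem cell and leukaemia), 2 and 0 with camera's preset and estimated correlation, and 1 with the Y share. With coverage of at least 20 the B cell list was not called (adjusted p = 0.115), and without the 3 libraries numbered 2 the imprinted list was called lower (0.0197) and the stromal list was not called (0.128).

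For CD11b-negative against PBS, calls were 123048 CpGs, 13966 tiles and 871 gene ends with the dispersion fixed at 1, 672 CpGs, 81 tiles, 1 gene end (Slc22a3, named after its value was seen) and 1 list with the Y share, 44 CpGs with the replicate block, 68 CpGs without the 3 libraries numbered 2, 15 CpGs, 3 tiles and 1 list without the CD11b libraries numbered 2, and 1 list with camera's preset correlation. The list was erythroid and megakaryocyte in each of these cases. Leaving out 1 library gave 0 to 15 CpGs, 0 to 3 tiles, 0 to 0 gene ends and 0 to 1 lists, with 15 CpGs, 3 tiles and 1 list without CD11b-negative 2 and 7 CpGs without CD11b-negative 3.

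For CD11b-positive against CD11b-negative, calls were 152046 CpGs, 15670 tiles and 1061 gene ends with the dispersion fixed at 1, 22 CpGs and 4 tiles (chromosome 1, 191833001, chromosome 3, 131466001, chromosome 5, 92318001, and chromosome 8, 121570001, 1000 bp each) with all groups in 1 fit, 2 CpGs (chromosome 5, 92318891, and chromosome 16, 95708722) at 5 to 95% methylation, 124 CpGs, 37 tiles and 2 lists (neutrophil, T and NK cell) with the Y share, and 88445 CpGs, 17728 tiles, 883 gene ends and 4 lists (germline, T and NK cell, erythroid and megakaryocyte, stromal) without the libraries numbered 2. These tiles and CpGs were named after their values were seen. Of the 2 lists called with the Y share, neutrophil was lower and T and NK cell higher in CD11b-positive. The block gave 72228 CpGs, 11790 tiles and 683 gene ends. Leaving out 1 library gave 0 to 77083 CpGs, 0 to 17798 tiles, 0 to 234 gene ends and 0 to 3 lists, the highest without CD11b-negative 2 in each case. Only 1 of the 4 CD11b-positive libraries correlated best with its own number.

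For CD11b libraries against PBS, number 4 was under the bound of 0.1 (r -0.0990 for CD11b-positive and -0.131 for CD11b-negative). Numbers 1 to 3 passed it, with r from 0.175 to 0.730 and from 0.342 to 0.772. For CD11b-positive against PBS the block in the quasi-binomial test also ended the calls at Ccdc60 (adjusted p = 0.0656), Zbtb33 (0.0630) and Blk (0.0550). It called 195262 CpGs, 30688 tiles and 1352 gene ends. In fry's test the block left 4 lists called, without the B cell list (adjusted p = 0.0645).

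With the Y share as a term, differences of CD11b-positive from PBS changed sign, and none was then called, at the tiles on chromosome 5 from 113310001 (10.5 points) and on chromosome 12 from 17881001 (5.35), and at Sgsm1 (10.5), Ccdc60 (1.92), Hs3st4 (5.53), Gm9222 (9.93), Dlk1 (9.997), Apba2 (3.41), Kazn (11.9), Slc2a13 (6.37), Cadm1 (3.95), Zbtb33 (5.04), Sfrp1 (8.40), Bcl11b (13.2), Cxcl12 (10.1), 4930415O20Rik (-4.62), Elane (-4.40) and Oasl1 (-6.37). Of the other values at named gene ends of this comparison, 1054 kept direction and call and 236 lost the call. All other alternatives kept the counts of calls within 1.5-fold. Uncalled differences changed sign 12 times at named gene ends of this comparison, 28 times for CD11b-negative against PBS and 13 times for CD11b-positive against CD11b-negative. The tests of uncalled lists changed direction 34, 35 and 36 times, and none of these values was called. Depth limits gene ends such as Tnni3, with 40 to 110 calls per library.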

Other observations

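The values with the Y share as a term and the stretches of chromosomes 2 and 9 below were chosen after the results were seen.

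The gene ends left with the Y share as a term had fitted differences of CD11b-positive from PBS of 31.6 points at Rhd (adjusted p = 0.0125), 26.1 at Ermap (adjusted p = 0.0334), 18.1 at Snx1 (adjusted p = 0.0327), 17.7 at Nme9 (adjusted p = 0.0327) and 16.2 at Slc22a3 (adjusted p = 0.00369), all higher in CD11b-positive, in the quasi-binomial test moderated as in limma. Rhd and Ermap encode blood group antigens of red cells, Snx1 a protein of endosome sorting, Nme9 a member of the nucleoside diphosphate kinase family and Slc22a3 an organic cation transporter. In a linear limma fit of percent methylation with the same term the changes were 26.7 ± 4.05 points (SE) at Rhd, 21.7 ± 4.32 at Ermap, 16.0 ± 3.32 at Snx1, 13.7 ± 3.22 at Nme9, 12.5 ± 2.53 at Slc22a3, and 16.9 ± 4.60 at Epor and 1.48 ± 1.88 at Nfe2 of the erythroid and megakaryocyte list, with adjusted p from 0.128 at Rhd to 0.844 at Nfe2, and that linear fit called 0 gene ends with the term and 0 without it (1273 and 4365 at an unadjusted p under 0.05). The tiles in Parp14 and Tbxas1 kept fitted differences of 44.6 points (adjusted p = 0.00348) and 33.1 points (adjusted p = 0.0238) with the term.

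Calls relative to the PBS mean on X were 0.739 ± 0.102 in CD11b-positive and 0.871 ± 0.201 in CD11b-negative (SD, n = 4 each), and mean methylation of autosomal gene ends was 12.3% ± 0.0905, 12.1% ± 0.192 and 11.8% ± 0.234 in CD11b-positive, CD11b-negative and PBS. The stretch of chromosome 2 from 90000001 to 100000000 held 1.2% ± 0.332 of the autosomal calls in CD11b-positive, 0.868% ± 0.531 in CD11b-negative and 0.574% ± 0.0806 in PBS, and that of chromosome 9 from 1 to 10000000 held 0.274% ± 0.0707, 0.218% ± 0.106 and 0.147% ± 0.00655. Over all 12 libraries, which form separate clusters, Spearman's rho of these shares with the Y share was 0.734 and 0.713. A test of the first rho was run, met neither of its bounds and is not weighed. The called Spi1 gene end (chromosome 2, 91114759 to 91116759) lies in the first stretch.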
